A study of Mus musculus with 9 samples.

How the data were processed

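RNA was measured on 9 Affymetrix gene arrays, each from 1 sample of conventional dendritic cells (cDC) sorted from the spleens of mice of strain 129SvEv/Tac. Of these arrays, 8 came from cDC2, with 2 arrays for each combination of genotype (wild type, WT, or Batf-/- Batf3-/- double knockout, DKO) and state (resting or activated), and 1 came from resting WT cDC1. Activated cells had been given IFN-gamma at 100 ng/ml for 1 h and then E. coli LPS at 1 µg/ml for 3 h more. Groups and replicate numbers were taken from the sample titles. The labels do not say whether the 2 arrays of a group came from separate mice, so the p-values measure the spread between these samples, which may be only technical. They also do not say whether resting cells were kept in culture for the same time as the activated cells.

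Biotin-labelled cDNA was made with a kit for very small RNA amounts, per the labels' protocols. The arrays were summarised with Affymetrix Expression Console and RMA, per the submitters' processing notes, which give no version. RMA corrects background, normalizes the arrays to a shared distribution and gives each transcript cluster (the probes of 1 gene locus) a single value. The deposited values are intensity values on a linear scale, 1 per transcript cluster and array, with array medians from 53.4 to 55.6. The design had foreseen log2 values, so log2 of each value was taken before any test, as had been laid down for a linear table. The log2 values of different arrays at the same rank differed by at most 0.31, with a median of 0.06, so the arrays had in effect been brought to a shared distribution before deposit. A difference in total RNA between groups is therefore not visible in these values. The number of arrays limits the precision: 2 per cDC2 group and 1 for cDC1.

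The table held 28853 transcript clusters, of which 21789 carried 1 gene symbol, 1621 carried several and 5443 carried none in the platform annotation. Older symbols were updated through the annotation of assembly GRCm38.p6, which served otherwise only to find which genes neighbour each other. Only clusters with 1 symbol entered the gene tests. For the 999 genes with several clusters, the cluster with the highest mean over all arrays was used. Of 19938 genes, 10728 had a group mean above the median of all values of such clusters (61.3 on the linear scale) in at least 1 group and were tested. The clusters with several symbols or none were tested apart, without names: 2773 passed the same brightness rule, with 0 genotype calls by limma in each genotype comparison and 34 in the mean of both states with the replicate number as a block.

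Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided), in 1 fit of all 9 arrays with a mean for each of the 5 groups and 4 residual degrees of freedom. P-values were adjusted by Benjamini-Hochberg over the genes tested, and adjusted p below 0.05 was the threshold. The comparisons were DKO against WT in resting cDC2, in activated cDC2 and as the mean of both states, activated against resting in WT and in DKO cDC2, the difference between those responses (interaction), and resting WT cDC1 against cDC2. In the last, the lone cDC1 array was assumed to vary as the cDC2 arrays do. Values are log2 differences with their standard error (SE) unless stated otherwise.

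For each comparison the genes named are Batf, Batf2, Batf3, Irf4 and Irf8, the 10 largest increases and 10 largest decreases past the threshold whose arrays do not overlap between the groups (for the interaction and the mean of both states, past the threshold alone), and up to 4 list members with the largest change past the threshold. Symbols of unnamed genes, microRNAs, small nucleolar RNAs, olfactory receptors and receptor gene segments were passed over. Where no list member passed, up to 2 with the smallest p are given as values, and where fewer than 5 genes passed in a direction, the genes of smallest p in it up to 5. The rule was also applied to the fit with the replicate number as a block, a use chosen after the data had been seen.

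Beyond single genes, 23 gene lists were drawn up: interferon-stimulated genes, IFN-gamma-responsive GTPases and regulators, inflammatory cytokines and chemokines, NF-kappaB feedback and signalling, dendritic cell maturation and co-stimulation, MHC class II presentation, MHC class I presentation, cDC1 markers, cDC2 markers, the AP-1 and BATF family with its IRF partners, dendritic cell transcription factors, the immediate early and dissociation response, glycolysis, cholesterol synthesis, cell cycle, and markers of plasmacytoid dendritic cells, B and plasma cells, T cells, NK cells, macrophages, monocytes, neutrophils and erythroid cells. The erythroid list had fewer than 5 genes tested and was not tested, leaving 22. Lists were tested with camera at a preset correlation of 0.01, adjusted over the lists of a comparison, and again with camera at an estimated correlation and with fry. Camera compares a list with the other genes, while fry tests whether a list's genes move on balance one way. The preset correlation takes list members to be nearly independent. With an estimated correlation, 1 list call of all comparisons held, that of cDC1 markers between cDC1 and cDC2.

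All groups of cDC2 share the replicate numbers 1 and 2. Deviations of same-numbered arrays from their group means correlated across genes in all 6 pairs of groups, with r from 0.454 to 0.695. Genes are not independent replicates, but every pair lay above 0.1, the bound set for treating the numbers as a pairing. The pairing comes from these correlations and not from a label. A fit of the 8 cDC2 arrays with the replicate number as a block (3 residual degrees of freedom) is therefore given beside a result where it changes a call or moves a count of calls by over 1.5 times.

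The samples and groups, the fits, the gene lists, the rule for named genes and the alternatives were chosen before the data were examined, except where an alternative or a test is said to have been chosen later. The alternatives were no brightness filter, a stricter one (8823 genes), the mean of all clusters of a gene (10631 genes), quantile normalization again, centring each array on its median, eBayes with trend and robust, array weights, a minimum log2 difference of 1, only the arrays of the groups compared, leaving out each array in turn, and the replicate block. For the lists, an alternative without Batf and Batf3 in the AP-1 and BATF list was added after the data had been seen.

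The fits were tested on simulated data of 10728 genes with 100 changed at each size. In resting cDC2, 77% of genes changed by a log2 of 1 and 98% of those changed by 2 were recovered. With a shift of assumed size shared by same-numbered arrays, these shares were 16% and 79%, and with the block 73% and 98%. False calls were 0 among 95 without the block and 14 among 185 with it. Over both states with that shift, the shares were 63% and 95%, and with the block 88% and 99%. False calls were 1 among 159 and 7 among 194. In 10 unchanged data sets without shift or block, at most 1 gene was called.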

Results

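Gene expression was measured on 9 arrays of dendritic cells sorted from mouse spleen, to find the genes that depend on the transcription factors BATF and BATF3 in conventional dendritic cells. The cells were cDC2, the subset that mainly presents antigen to CD4 T cells, from WT mice and from mice lacking both factors (DKO). They were either resting or activated with IFN-gamma and LPS, with 2 arrays in each of the 4 groups. A single array of resting WT cDC1, the subset specialised in cross-presentation to CD8 T cells and dependent on BATF3 for its development, served as a reference for subset genes. The number of arrays limits the precision of every value. Across the 4 cDC2 groups, replicate arrays correlated at r = 0.969 to 0.980 across genes, which are not independent replicates.

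The targeted genes were lower in all DKO arrays than in all WT arrays. Batf read 5.40 and 5.44 (log2 intensity, replicates 1 and 2) in resting DKO and 5.44 and 5.31 in activated DKO cDC2. It read 6.74 and 7.37 in resting WT, 7.26 and 9.07 in activated WT cDC2 and 7.17 in cDC1. Batf3 read 6.43 and 7.17 in resting DKO and 6.65 and 6.90 in activated DKO. In the other groups it read 7.71 and 7.58 in resting WT, 8.56 and 9.92 in activated WT and 8.59 in cDC1. Where the probes of either gene lie relative to the deleted part is not known. Signal that remains in DKO arrays, as for Batf3, may be transcript outside the deletion or background. Among their relatives and partners, Batf2 read 6.19 to 6.87 in resting and 7.86 to 8.08 in activated cDC2 of either genotype. Irf4 lay between 9.37 and 11.02 in all cDC2 arrays and at 5.13 in cDC1. Irf8 read 7.64 to 8.46 in resting cDC2, 11.67 to 12.27 in activated cDC2 and 9.94 in cDC1.

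**Figure D1:**
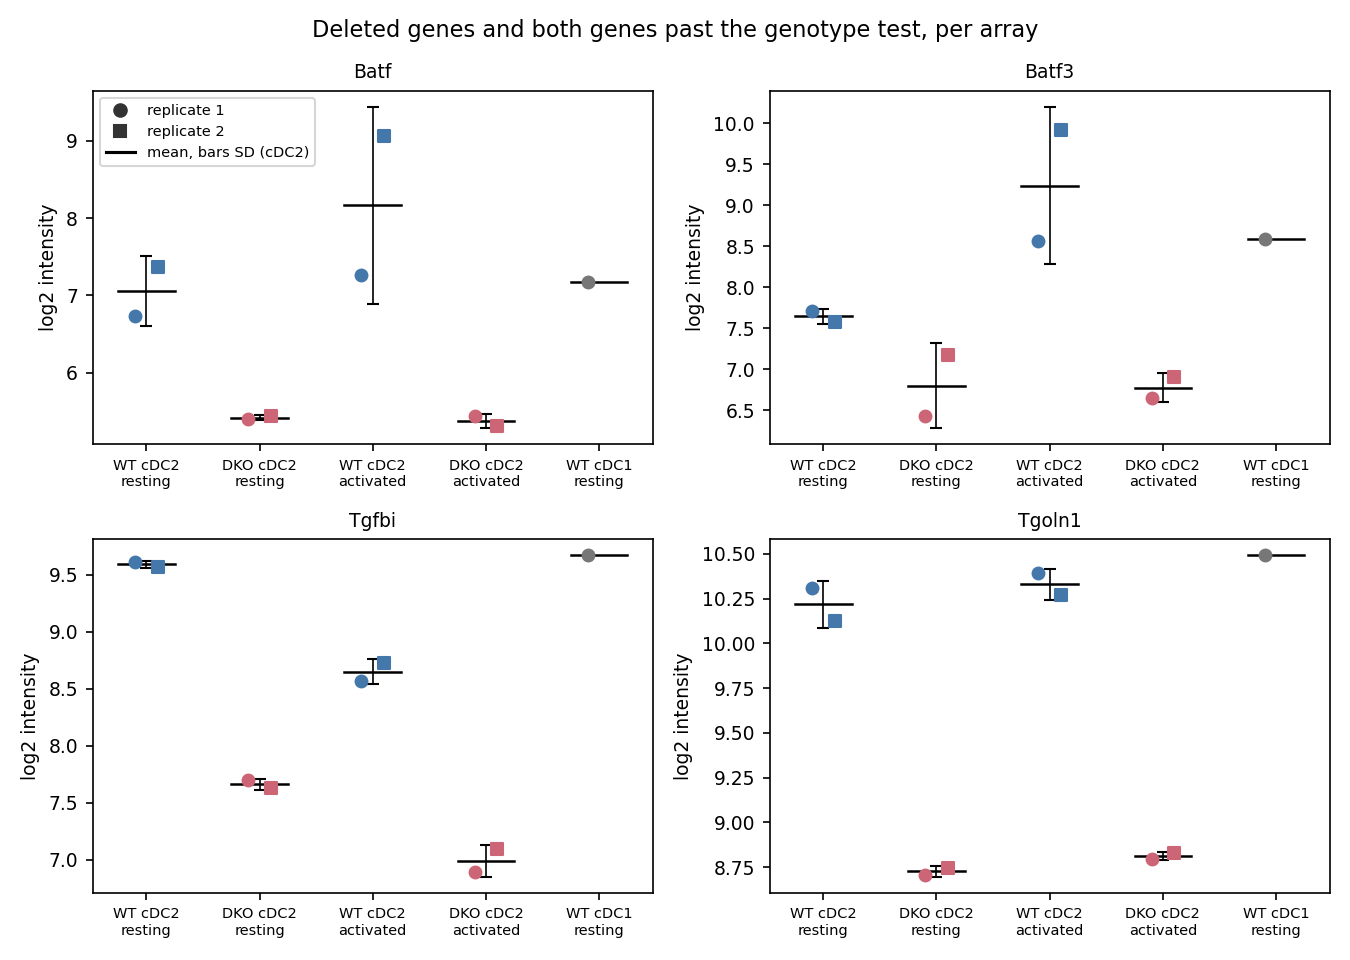
Log2 intensity of Batf, Batf3, Tgfbi and Tgoln1 on each of the 9 arrays by group, with circles for replicate 1, squares for replicate 2, lines for means and bars for the SD. Batf stays between 5.31 and 5.44 in the 4 DKO arrays and at 6.74 or above in the others, and Tgfbi averages 7.66 in resting DKO against 9.59 in resting WT cDC2.

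The first comparison asked which genes differ between DKO and WT cDC2 at rest (2 arrays against 2). Tgfbi, which codes for a TGF-beta-induced extracellular matrix protein, fell by 1.93 ± 0.11 (adjusted p = 0.0134), from a log2 intensity of 9.59 ± 0.03 (SD) to 7.66 ± 0.05. Tgoln1, which codes for a membrane protein of the trans-Golgi network, fell by 1.49 ± 0.10 (adjusted p = 0.0225), from 10.22 ± 0.13 to 8.73 ± 0.03. These were the 2 genes that changed, and 0 genes rose by limma, with 707 genes at an unadjusted p under 0.05. Batf itself differed by -1.64 ± 0.54 (adjusted p = 0.654) and Batf3 by -0.84 ± 0.45 (adjusted p = 0.907), neither past the threshold. Batf2 (-0.36 ± 0.16), Irf4 (0.04 ± 0.23) and Irf8 (0.20 ± 0.33) did not pass either.

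Of the genes that did not pass, those of smallest p on the higher side in resting DKO cells were Sucnr1 at 1.39 ± 0.14, Pxdc1 at 1.09 ± 0.13 and Gramd4 at 0.90 ± 0.12. With them came Gfra2 at 1.24 ± 0.17 and Pdcd1lg2, which codes for the PD-1 ligand PD-L2, at 0.97 ± 0.14 (adjusted p from 0.162 to 0.225). On the lower side they were Cd36 at -0.86 ± 0.10, Tmem140 at -1.21 ± 0.14 and Plce1 at -0.84 ± 0.10 (adjusted p from 0.172 to 0.185). With the replicate number as a block, all 8 passed (adjusted p from 0.0144 to 0.0355). In that fit 34 genes were higher and 45 lower in DKO. The largest of these by the block fit were Upp1 at 1.67, Sema4a at 1.52, Tarm1 at 1.47 and Klri1 at 1.45 on the higher side. On the lower side, Rsad2 stood at -1.99 ± 0.28 and the chemokines Cxcl11 and Ccl3 at -1.51 and -1.23. Others were Heatr9 at -1.48, Adap2 at -1.42, Pmepa1 at -1.41 and Plau at -1.24. Leaving out 1 array at a time in the fit without the block, Tgfbi stayed between -1.96 and -1.89 and passed only without WT resting replicate 1 (adjusted p = 0.0463, otherwise up to 0.36). Tgoln1 stayed between -1.59 and -1.40 and passed in none (adjusted p from 0.0588 to 0.427). The number of genes past the threshold was then 6 without WT resting replicate 1 and 0 without each of the other 3 arrays. At an unadjusted p under 0.05 there were 598, 430 and 643 genes without DKO replicate 1, DKO replicate 2 and WT replicate 2.

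As lists, interferon-stimulated genes stood lower in resting DKO than WT cDC2 in all 30 members tested. Their median was -0.98 (camera adjusted p = 1.6e-19; 0.19 with an estimated correlation, below called estimated). None of the 30 passed over all genes, and adjusted over the list alone 9 were lower, with Ifit2 at -2.12 ± 0.36 and Rsad2 at -1.99 ± 0.34. IFN-gamma-responsive GTPases and regulators had a median of -0.25 (adjusted p = 6.6e-05; estimated 0.292). Gbp7 stood at -1.56 ± 0.58 and Gbp5 at -1.35 ± 0.51, and 0 of 18 passed over all genes or adjusted over the list alone. MHC class I presentation genes had a median of -0.18 (adjusted p = 0.0402; estimated 0.489), with 0 of 17 past the threshold both ways. Erap1 stood at -0.35 and Pdia3 at -0.28. These lists moved with 1 array. On WT resting replicate 2 the interferon-stimulated list averaged 11.05, against 9.67 on WT resting replicate 1 and 9.11 and 9.39 on the DKO resting arrays. Without WT resting replicate 2 the median of the interferon list was -0.20 (adjusted p = 1.3e-05), that of the IFN-gamma list -0.03 (adjusted p = 0.152) and that of the MHC class I list 0.16 (adjusted p = 0.341). With WT resting replicate 1 left out they were -1.78, -0.54 and -0.43, and with DKO resting replicate 1 left out the MHC class I median was 0.00 (adjusted p = 0.486).

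**Figure D2:**
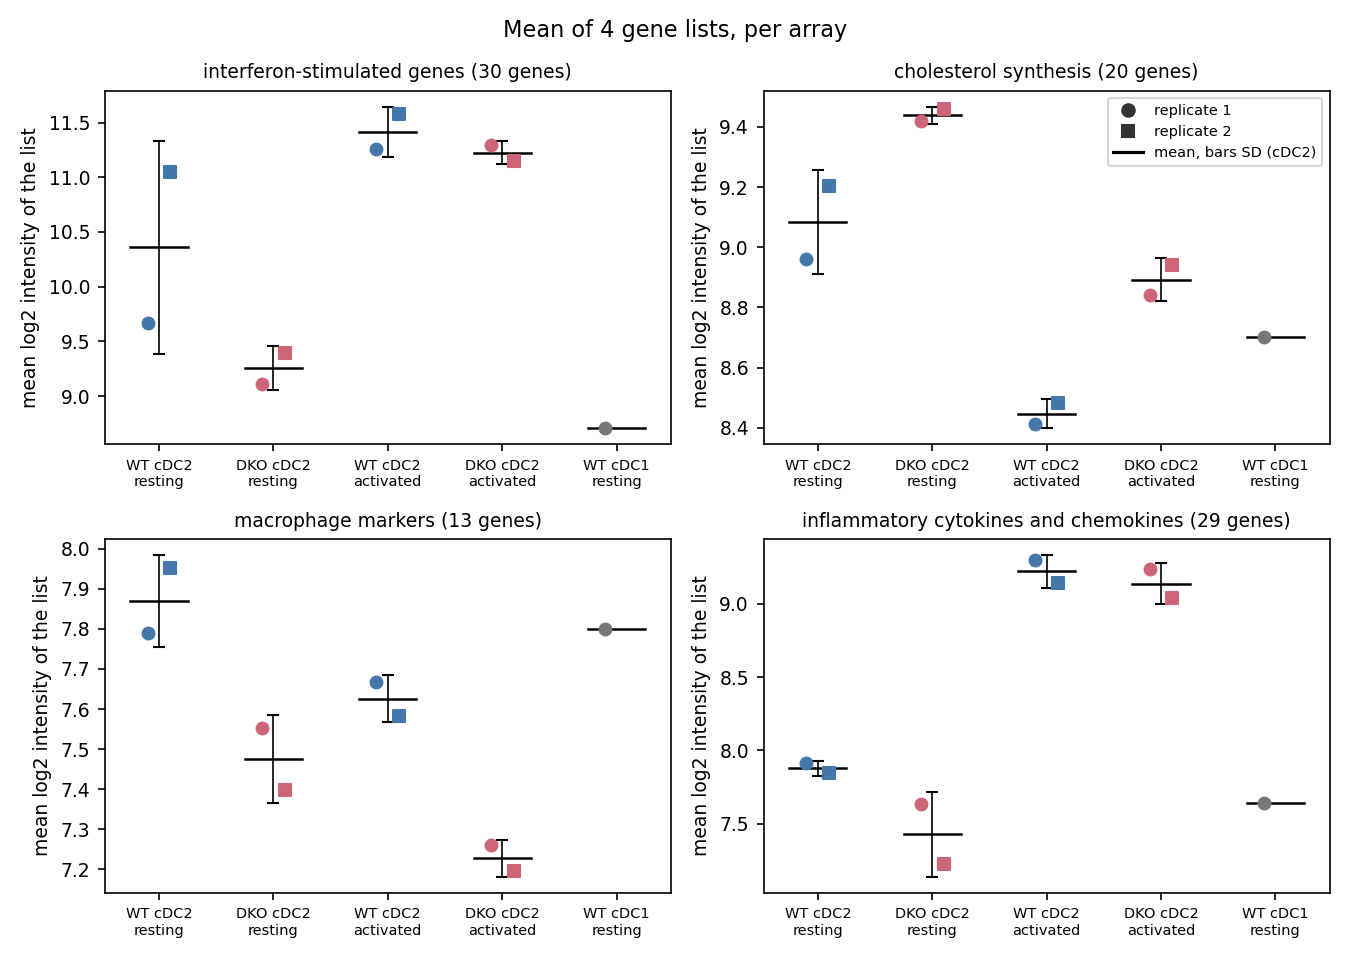
Mean log2 intensity per array of 4 gene lists, with circles for replicate 1, squares for replicate 2 and lines for group means. The interferon-stimulated list averages 11.05 on WT resting replicate 2 and 9.67 on WT resting replicate 1, and the cholesterol synthesis list lies at 9.42 and 9.46 in resting DKO against 8.96 and 9.21 in resting WT cDC2.

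Genes of cholesterol synthesis stood higher in all 20 members. Their median was 0.34 (adjusted p = 1.6e-09; estimated 0.145). None passed alone or adjusted over the list alone, with Idi1 at 0.87 ± 0.22 and Hsd17b7 at 0.46 ± 0.11. Cell cycle genes had a median of 0.25 (adjusted p = 1.0e-06; estimated 0.3), with 0 of 28 past the threshold both ways. Top2a stood at 0.73 ± 0.15 and Ccna2 at 0.72 ± 0.17. Inflammatory cytokines and chemokines had a median of -0.32 (adjusted p = 1.5e-06; estimated 0.145). Of 29 members 3 were lower adjusted over the list alone and 0 over all genes, with Cxcl11 at -1.51 ± 0.19 and Ccl5 at -0.58 ± 0.09. Leaving out WT resting replicate 1, the medians of these 3 lists were 0.19, 0.16 and -0.17. The cell cycle median was 0.41, 0.10 and 0.38 without DKO resting replicate 1, DKO resting replicate 2 and WT resting replicate 2. The cytokine median was -0.50 and -0.21 without DKO resting replicates 1 and 2.

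The AP-1 and BATF family with its IRF partners had a median of -0.26 (adjusted p = 2.4e-04; estimated 0.145), with Jdp2 at -0.53 ± 0.12 and Mafk at -0.55 ± 0.17. Of the markers of other cells, plasmacytoid dendritic cell genes had a median of -0.58 (adjusted p = 0.00215), with Tcf4 at -0.88 ± 0.16 and Lag3 at -1.25 ± 0.30. Macrophage genes had a median of -0.50 (adjusted p = 4.1e-04), with C1qb at -0.75 ± 0.20 and C1qa at -0.74 ± 0.21. Monocyte genes had one of -0.17 (adjusted p = 0.00656), with Ace at -0.62 ± 0.16 and Lyz2 at -0.68 ± 0.34. With an estimated correlation each of these 3 lists had an adjusted p of 0.145. Immediate early and dissociation genes (median -0.15, adjusted p = 0.00641), cDC2 markers (-0.14, adjusted p = 0.028), cDC1 markers (-0.02, adjusted p = 0.0159) and maturation genes (0.15, adjusted p = 0.0254) also passed. With an estimated correlation their adjusted p was 0.26, 0.225, 0.145 and 0.502. The cDC1 list holds Batf3, a deleted gene. In none of these 8 lists did a member pass over all genes. Adjusted over the list alone, 2 cDC1 markers and 2 plasmacytoid genes were lower and 1 plasmacytoid gene and 1 maturation gene higher. DKO resting replicate 1, left out, ended the cDC1 marker call (-0.08, adjusted p = 0.0575). It gave -0.30 for cDC2 markers, -0.27 for immediate early genes and -0.32 for monocyte genes. DKO resting replicate 2, left out, ended the calls of the AP-1 list (-0.13, adjusted p = 0.0658), cDC2 markers (0.01, adjusted p = 0.389), immediate early genes (-0.08, adjusted p = 0.389) and maturation genes (0.09, adjusted p = 0.314). It gave -0.09 for cDC1 markers and -0.11 for monocyte genes. WT resting replicate 1, left out, ended those of cDC2 markers (-0.01, adjusted p = 0.233), immediate early genes (-0.17, adjusted p = 0.0973) and maturation genes (-0.01, adjusted p = 0.855). It gave -0.16 for the AP-1 list and -0.09 for cDC1 markers. WT resting replicate 2, left out, ended those of cDC1 markers (-0.04, adjusted p = 0.0964) and plasmacytoid genes (-0.37, adjusted p = 0.0881). It gave -0.32 for macrophage, -0.10 for monocyte and 0.31 for maturation genes.

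The other 8 lists did not pass. MHC class II genes had a median of -0.06 (adjusted p = 0.0562). The medians of the others were: dendritic cell transcription factors -0.02, NF-kappaB genes 0.01, glycolysis genes 0.02, B and plasma cell genes 0.01, T cell genes 0.00, NK cell genes 0.39 and neutrophil genes 0.05 (adjusted p from 0.323 to 0.911 for these 7). The means and the tests of the glycolysis, B cell and T cell lists pointed down while their medians lay just above 0, and the medians of the NF-kappaB, B cell and T cell lists changed sign with another scaling. Leaving out DKO resting replicate 1, the transcription factor list passed at -0.16 (adjusted p = 0.0333). In the fit with the replicate block, the call of cDC2 markers was lost (adjusted p = 0.0963) and that of MHC class II genes gained (adjusted p = 0.038). Single members passed in that fit: 1 interferon, 2 cytokine, 1 cDC1, 2 cDC2, 2 AP-1, 1 transcription factor, 2 immediate early and 2 plasmacytoid genes were lower and 1 each of the maturation, cDC2, cholesterol, cell cycle and NK cell lists higher. By fry, 0 lists passed, against 14 by camera with the preset correlation.

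In activated cDC2 (2 arrays against 2), the same question gave the same pair of genes. Tgfbi fell by 1.66 ± 0.11 and Tgoln1 by 1.52 ± 0.10 in DKO cells (adjusted p = 0.0202 for both). By limma 0 genes rose, with 638 genes at an unadjusted p under 0.05. Batf was at -2.79 ± 0.54 (adjusted p = 0.457) and Batf3 at -2.47 ± 0.45 (adjusted p = 0.451), neither past the threshold. The WT replicates lay as far apart as 7.26 and 9.07 for Batf. Batf2 stood at -0.08 ± 0.16, Irf4 at 0.38 ± 0.23 and Irf8 at 0.08 ± 0.33. Next by p, on the higher side and not past the threshold, came Idi2 at 2.19 ± 0.28, Upp1 at 1.83 ± 0.25 and Cldn1 at 1.19 ± 0.16. They were followed by Dstn at 0.74 ± 0.11 and Grpr at 0.58 ± 0.09 (adjusted p from 0.382 to 0.424). On the lower side came Dap at -0.86 ± 0.09, Vav1 at -1.06 ± 0.14 and Mylip at -1.38 ± 0.19 (adjusted p from 0.169 to 0.382).

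With the replicate number as a block, 30 genes were higher and 31 lower in activated DKO cDC2. Batf3 passed in that fit (adjusted p = 0.0394) and Batf did not (adjusted p = 0.0551). The genes just named passed except Grpr (adjusted p = 0.0507). Others of the largest block calls were Abca13 at 1.93, Strip2 at 1.48, Klk1b22 at 1.47, Serpinb9b at 1.41, Sema4a at 1.39 and Idi1 at 1.18 on the higher side. Fcgr4 stood at -1.44, Ms4a7 at -1.22, Bach1 at -1.05 and Cd300a at -1.0. Leaving out each of the 4 arrays in turn in the fit without the block left 0 genes past the threshold by limma. At an unadjusted p under 0.05 there were 732 and 421 genes without DKO activated replicates 1 and 2 and 502 and 698 without WT activated replicates 1 and 2. Tgfbi then lay between -1.76 and -1.56 (adjusted p from 0.174 to 0.401) and Tgoln1 between -1.58 and -1.46 (adjusted p from 0.188 to 0.401).

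Of the lists, cholesterol synthesis was again higher in all 20 members in activated DKO cDC2. Its median was 0.40 (adjusted p = 2.9e-13; estimated 0.167), with Idi1 at 1.18 ± 0.22 and Hsd17b7 at 0.73 ± 0.11. Adjusted over the list alone 5 of them passed and 0 over all genes. Macrophage genes had a median of -0.42 (adjusted p = 5.1e-04; estimated 0.167), with 2 lower adjusted over the list alone. C1qc and C1qb stood at -0.67 ± 0.16 and -0.85 ± 0.20. Monocyte genes had one of -0.24 (adjusted p = 0.00666; estimated 0.167), with Lyz2 at -0.78 ± 0.34 and Ace at -0.35 ± 0.16. The AP-1 and BATF list had a median of -0.19 (adjusted p = 1.6e-04; estimated 0.167), with 3 members lower adjusted over the list alone. cDC2 markers had a median of -0.20 (adjusted p = 0.00666), with Cd300a at -1.0 ± 0.24 and Mgl2 at -1.12 ± 0.28. Immediate early genes had one of -0.15 (adjusted p = 0.0147), with Fosb at -0.38 ± 0.19. MHC class II genes had one of -0.09 (adjusted p = 0.017), with Ctsb at -0.53 ± 0.09 and H2-Eb1 at -0.27 ± 0.12. With an estimated correlation the adjusted p of these 3 was 0.179, 0.349 and 0.179. Adjusted over the list alone, 1 MHC class II gene passed and none of the others. The MHC class II call was lost without DKO activated replicate 1 (-0.12, adjusted p = 0.103) and WT activated replicate 1 (-0.09, adjusted p = 0.219). Its median was -0.14 without WT activated replicate 2. The cDC2 marker call was lost without DKO activated replicate 2 (-0.10, adjusted p = 0.102) and WT activated replicate 1 (-0.10, adjusted p = 0.0869). The immediate early call was lost without the same arrays (-0.03, adjusted p = 0.218, and -0.10, adjusted p = 0.0925). The monocyte call was lost without DKO activated replicate 2 (-0.11, adjusted p = 0.175). Without WT activated replicate 2 the AP-1 median was -0.36 and the macrophage median -0.22.

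The remaining 15 lists did not pass in activated cells, among them interferon-stimulated genes at -0.13 (adjusted p = 0.0668), with Ifit2 at -0.44 ± 0.36. IFN-gamma-responsive genes stood at -0.09 (adjusted p = 0.136), with Cd274 at -0.37 ± 0.09 and Irf1 at -0.38 ± 0.16. Maturation genes stood at 0.07 (adjusted p = 0.12), with Ccl22 at 0.41 ± 0.09 and Anxa3 at 0.56 ± 0.14. Plasmacytoid genes stood at -0.16 (adjusted p = 0.0698) and cDC1 markers at -0.05 (adjusted p = 0.0668). Further medians were those of cytokines at -0.11, MHC class I genes at -0.10, cell cycle genes at 0.08, transcription factors at -0.07, NF-kappaB genes at 0.04, glycolysis genes at -0.01, and B, T, NK cell and neutrophil genes at 0.13, -0.05, 0.03 and 0.07, of which that of NK cells changed sign with another scaling. In the fit with the replicate block, maturation genes (adjusted p = 0.0398) and plasmacytoid genes (adjusted p = 0.021) passed as well. As single members, 3 AP-1 genes and 1 each of the cytokine, cDC1, cDC2, immediate early and plasmacytoid lists were lower there and 1 each of the maturation, cholesterol and NK cell lists higher. Without DKO activated replicate 1 the interferon list passed at -0.23 (adjusted p = 0.0101) and the maturation list at 0.17 (adjusted p = 0.0319). The latter also passed without WT activated replicate 2, at 0.30 (adjusted p = 0.0215). By fry 0 lists passed, against 7 by camera with the preset correlation.

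The mean of both states (4 arrays against 4) asked for genes that differ by genotype whatever the state. Tgfbi fell by 1.79 ± 0.08 (adjusted p = 0.00241) and Tgoln1 by 1.51 ± 0.07 (adjusted p = 0.00245) in DKO cDC2, each lower in all 4 same-numbered pairs of arrays. By limma 0 genes rose, with 1157 genes at an unadjusted p under 0.05. Batf stood at -2.21 ± 0.39 (adjusted p = 0.126), Batf3 at -1.66 ± 0.32 (adjusted p = 0.148), Batf2 at -0.22 ± 0.11, Irf4 at 0.21 ± 0.16 and Irf8 at 0.14 ± 0.23. Just short of the threshold, at adjusted p = 0.061 each, were Upp1 at 1.75 ± 0.18, Cldn1 at 1.14 ± 0.12, Idi2 at 1.89 ± 0.20, Dstn at 0.69 ± 0.08 and Mcemp1 at 0.60 ± 0.07. On the lower side at that value were Dap at -0.67 ± 0.06, Ms4a7 at -1.21 ± 0.13 and Mylip at -1.27 ± 0.14. Both calls held without each of the 8 arrays in turn, with Tgfbi between -1.84 and -1.74 and Tgoln1 between -1.55 and -1.46. The number of calls was 4 without DKO resting replicate 1 and without WT resting replicate 1.

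With the replicate number as a block, 320 genes were higher and 279 lower in DKO cDC2 over both states. Batf and Batf3 (adjusted p = 0.0161 for both) were among them. The largest on the higher side were Idi2, Upp1, Abca13 at 1.49, Sema4a at 1.46 ± 0.12 and Serpinb9b at 1.38 ± 0.11. Next were Klk1b22 at 1.33, Strip2 at 1.28, Tarm1 at 1.27, Mfge8 at 1.24 and Lxn at 1.18. On the lower side, after Batf, Tgfbi, Batf3 and Tgoln1, came Ifit2 at -1.28 ± 0.25, Mylip, Chic1 at -1.25, Ehf at -1.23, Ms4a7 and Slamf8 at -1.18. Macrophage genes called were Slc40a1 at -1.07 ± 0.12, C1qb at -0.80 ± 0.10, Hmox1 at -0.70, C1qa at -0.65 and C1qc at -0.53. None of the 13 was higher. In cholesterol synthesis, 9 of 20 genes were higher and none lower, led by Idi1 at 1.02 ± 0.08, Lss at 0.64, Mvd at 0.60 and Hsd17b7 at 0.59. Of the AP-1 and BATF list 7 of 22 were lower and none higher, with Bach1 at -0.83, Atf3 at -0.71 and Jdp2 at -0.53 beside the deleted genes. Of the maturation list 7 of 25 were higher and none lower, with Cd70 at 1.11, Tnfrsf4 at 0.55, Pdcd1lg2 at 0.51 and Anxa3 at 0.47. Of the cDC2 markers 5 were lower, with Clec12a (higher in cDC1 than cDC2) at -0.93 ± 0.08, Mgl2 and Cd300a at -0.91 and Cd4 at -0.67, and 2 higher. Also lower were 2 interferon, 3 cytokine, 2 MHC class II, 4 cDC1, 2 transcription factor, 3 immediate early, 2 glycolysis, 3 plasmacytoid, 1 T cell and 2 monocyte genes, and higher 4 cell cycle genes and 1 each of the cytokine, NF-kappaB, transcription factor and NK cell lists.

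As lists over both states, cholesterol synthesis had a median of 0.37 (adjusted p = 1.1e-12; estimated 0.143), with 11 of 20 higher adjusted over the list alone. Macrophage genes had one of -0.53 (adjusted p = 1.7e-04; estimated 0.143), with 5 of 13 lower adjusted over the list alone. Monocyte genes had one of -0.21 (adjusted p = 0.00131; estimated 0.143). Interferon-stimulated genes stood at -0.56 (adjusted p = 2.4e-11; estimated 0.276), with 5 of 30 lower adjusted over the list alone. IFN-gamma-responsive genes stood at -0.26 (adjusted p = 0.00131; estimated 0.427). The AP-1 and BATF list stood at -0.21 (adjusted p = 5.3e-05), plasmacytoid genes at -0.40 (adjusted p = 0.00503) and cDC1 markers at -0.02 (adjusted p = 0.0135), each at adjusted p = 0.143 with an estimated correlation. cDC2 markers stood at -0.17 (adjusted p = 0.00503) and MHC class II genes at -0.07 (adjusted p = 0.0135), at adjusted p = 0.154 and 0.147 with an estimated correlation. Cytokines stood at -0.19 (adjusted p = 3.1e-04) and immediate early genes at -0.14 (adjusted p = 0.00184), both at adjusted p = 0.22 with an estimated correlation. Cell cycle genes stood at 0.17 (adjusted p = 0.00123) and maturation genes at 0.11 (adjusted p = 0.0288), at adjusted p = 0.517 and 0.533 with an estimated correlation. Over all genes no member of these 14 lists passed without the block. Adjusted over the list alone, 4 members of the AP-1 list, 4 of the plasmacytoid, 5 of the cDC2, 3 of the cDC1, 2 of the cytokine and 1 each of the MHC class II and maturation lists were lower. On the higher side were 5 of the maturation list and 1 each of the cDC2 and cytokine lists. By fry, 4 lists passed: cholesterol synthesis, macrophage and monocyte genes (adjusted p = 0.0381 each) and cDC1 markers (adjusted p = 0.0462).

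The 8 lists that did not pass over both states were MHC class I genes at -0.11 (adjusted p = 0.0668), NF-kappaB genes at 0.01, transcription factors at -0.02, glycolysis genes at 0.03, and B, T, NK cell and neutrophil genes at 0.05, 0.01, 0.20 and 0.08. The glycolysis and T cell lists had medians above 0 while their means and tests pointed down, and the NF-kappaB and T cell medians changed sign with another scaling. In the fit with the replicate block, the MHC class I list passed (adjusted p = 0.0343) and the cDC1 marker call was lost (adjusted p = 0.0589). Leaving out WT resting replicate 2 gave -0.20 for the interferon list (adjusted p = 2.3e-05), -0.06 for the IFN-gamma list, 0.24 for the maturation list. The cDC1 marker call was then lost (-0.02, adjusted p = 0.0504). With WT resting replicate 1 left out, the interferon list was at -0.99, cDC1 markers at -0.09 and cDC2 markers at -0.10. The MHC class I list then passed at -0.23 (adjusted p = 1.6e-04) and the maturation call was lost (0.04, adjusted p = 0.416). Leaving out DKO resting replicate 1, the cytokine list was at -0.30, the monocyte list at -0.35 and cDC1 markers at -0.03. Leaving out DKO resting replicate 2, the maturation call was lost (0.08, adjusted p = 0.13) and the MHC class I list passed (-0.13, adjusted p = 0.0176). MHC class II genes were then at -0.10, cDC1 markers at -0.07 and cDC2 markers at -0.11. Without DKO activated replicate 1 the MHC class II call was lost (-0.05, adjusted p = 0.053) and monocyte genes were at -0.37. Without DKO activated replicate 2 the maturation call was lost (0.10, adjusted p = 0.118) and the MHC class I list passed (-0.13, adjusted p = 0.048). Here cDC1 markers were at -0.05 and cDC2 markers at -0.10. Without WT activated replicate 1 the maturation call (0.11, adjusted p = 0.216) and the MHC class II call (-0.07, adjusted p = 0.0747) were lost, and the MHC class I list passed (-0.15, adjusted p = 0.0359). In that fit cDC1 markers were at -0.04 and monocyte genes at -0.35. Without WT activated replicate 2 the IFN-gamma call was lost (-0.25, adjusted p = 0.0514), maturation genes were at 0.23 and MHC class II genes at -0.11.

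Activation was then compared with rest within WT cDC2 (2 arrays against 2), which gives the response to IFN-gamma and LPS in cells with both factors. The largest increases were those of Cxcl9, a chemokine that draws T cells, at 4.93 ± 0.32, the interferon-inducible GTPase gene Iigp1 at 4.70 ± 0.35, Hamp at 4.32 ± 0.31 and Irf8 at 4.04 ± 0.33. They were followed by Calhm6 at 3.91 ± 0.31, Tbx21 at 3.85 ± 0.35, the cytokine genes Il6 at 3.81 ± 0.16 and Tnfsf15 at 3.62 ± 0.19, Gbp4 at 3.57 ± 0.54 and Upp1 at 3.52 ± 0.25 (adjusted p from 5.2e-04 to 0.0171). The largest decreases were those of Ceacam1 at -2.82 ± 0.49, Scd2 at -2.75 ± 0.46, Myo1f at -2.22 ± 0.28, Acss2 at -2.16 ± 0.28 and Ccr9 at -2.09 ± 0.43. They were followed by Lipa at -2.08 ± 0.37, Slc43a2 at -2.02 ± 0.18, Chst2 at -1.93 ± 0.15, Ivns1abp at -1.89 ± 0.44 and Foxred2 at -1.88 ± 0.18 (adjusted p from 0.00355 to 0.0464). Batf2 rose by 1.28 ± 0.16 (adjusted p = 0.0108). Batf3 at 1.60 ± 0.45 (adjusted p = 0.0724) and Irf4 at 0.86 ± 0.23 (adjusted p = 0.0642) did not pass but did with the replicate number as a block (adjusted p = 0.0111 and 0.0252). Batf at 1.11 ± 0.54 passed in neither fit (adjusted p = 0.228 and 0.0853).

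IFN-gamma-responsive GTPases and regulators rose in 12 of 18 members (17 adjusted over the list alone), with a median of 1.66 (adjusted p = 2.8e-15; estimated 0.131). Inflammatory cytokines and chemokines rose in 10 of 29 (13 adjusted over the list alone, 17 with the block), with a median of 1.21 (adjusted p = 1.4e-10; estimated 0.131) and Cxcl11 at 3.01 ± 0.19. Interferon-stimulated genes were higher in all 30 members with a median of 0.90 (adjusted p = 1.1e-09; estimated 0.394). Over all genes 2 rose, Cxcl10 by 2.62 ± 0.60 and Ifit2 by 1.5 ± 0.36, against 8 adjusted over the list alone and 14 with the replicate block. NF-kappaB feedback genes rose in 6 of 24 (11 adjusted over the list alone, 15 with the replicate block), with a median of 0.49 (adjusted p = 6.2e-09; estimated 0.131), with Socs3 at 2.50 ± 0.25 and Nfkbiz at 2.07 ± 0.17. Of the maturation genes, 6 of 25 rose and 1 fell (9 and 3 adjusted over the list alone; 12 and 3 with the block), with a median of 0.30 (adjusted p = 2.8e-04; estimated 0.395). Members that rose were Il15ra at 1.96 ± 0.38, Cd70 at 1.69 ± 0.33, Cd274 (PD-L1) at 1.24 ± 0.09 and Pdcd1lg2 at 1.19 ± 0.14. MHC class I genes had a median of 0.30 (adjusted p = 0.00494; estimated 0.41) and 0 of 17 past the threshold both ways, against 7 higher and 2 lower with the block. Nlrc5 stood at 1.15 ± 0.31. Leaving out WT resting replicate 1, the medians were 0.18 for the interferon list, 0.79 for cytokines, 0.11 for maturation and 0.08 for MHC class I genes, whose call was lost (adjusted p = 0.0818). Leaving out WT resting replicate 2, they were 1.65 for the interferon, 0.54 for the maturation and 0.60 for the MHC class I list, and without WT activated replicate 1 the maturation median was 0.47.

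Cholesterol synthesis genes fell in 10 of 20 members on activation of WT cells (12 adjusted over the list alone, 16 with the block), with a median of -0.50 (adjusted p = 4.9e-06; estimated 0.234). Among them were Mvd at -1.42 ± 0.20, Dhcr7 at -1.32 ± 0.20, Lss at -1.29 ± 0.25 and Cyp51 at -1.04 ± 0.15. Of the AP-1 and BATF list 4 of 22 rose (8, and 1 lower, adjusted over the list alone; 10 and 2 with the block), with a median of 0.35 (adjusted p = 3.9e-05; estimated 0.131), with Mafk at 1.48 ± 0.17 and Jdp2 at 0.64 ± 0.12. Of the immediate early genes 4 of 27 rose, the same number adjusted over the list alone and 10, with 2 lower, with the block, with a median of 0.21 (adjusted p = 3.8e-04; estimated 0.231). Among them were Klf6 at 1.19 ± 0.15 and Dusp2 at 0.93 ± 0.17. Of the dendritic cell transcription factors 4 of 24 rose and 2 fell (5 and 3 adjusted over the list alone; 8 and 4 with the block), with a median of 0.13 (adjusted p = 0.0127; estimated 0.231). Among them were Mycl at 1.52 ± 0.16, Tcf4 at 1.47 ± 0.16 and Cebpa at -0.82 ± 0.19. The cDC1 marker list had a median of 0.07 (adjusted p = 0.00494; estimated 0.131), with 3 members of 29 that rose and 1 that fell (5 and 2 adjusted over the list alone; 7 and 3 with the block). Those that rose were Irf8, Gpr33 at 2.70 ± 0.35 and Ifi205 at 1.45 ± 0.33, and Cd36 fell by 0.92 ± 0.10. Left out, WT resting replicates 1 and 2 and WT activated replicate 2 gave 0.14, 0.13 and 0.24 for the cDC1 list. Without WT resting replicate 2 and WT activated replicate 1 the immediate early median was 0.05 and 0.11, and without WT activated replicate 2 that of the transcription factors was 0.21.

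The other 11 lists did not pass in WT activation. MHC class II genes had a median of -0.07. Past the threshold were Ctsd at -1.43 ± 0.18, Ifi30 at -0.79 ± 0.17 and H2-DMa at 0.49 ± 0.10. Of the cDC2 markers (median -0.21) 6 fell and 1 rose. Among them were Cx3cr1 at -1.31 ± 0.20, Cd300a at -1.10 ± 0.24, Csf1r at -0.99 ± 0.19 and Tbx21. Glycolysis genes had a median of -0.24 and a mean of 0.03. Past the threshold were Hk2 at 2.22 ± 0.22 and Hk3 at 1.42 ± 0.21 and Slc16a3 at -0.79 ± 0.10. Cell cycle genes stood at -0.29 (adjusted p = 0.256) with 0 of 28 past the threshold by limma, against 3 higher and 7 lower with the block. They passed without WT resting replicate 1 (-0.36, adjusted p = 0.0242). Plasmacytoid genes stood at -0.19, with Ccr9, Lag3 at 1.49 ± 0.30, Tcf4 and Spib at -0.80 ± 0.16 past the threshold. T cell genes stood at -0.13, with Thy1 at 0.57 ± 0.12, and for both lists the test pointed up. NK cell genes stood at 0.08, B cell genes at -0.08, and macrophage genes at -0.05, with Treml4 at -1.04 ± 0.24. Monocyte genes stood at 0.13, with Fn1 at 1.16 ± 0.25, Itga4 at 0.78 ± 0.16 and Spn at -0.64 ± 0.11, and neutrophil genes at 0.12. With another scaling the MHC class II, B cell, T cell and macrophage medians changed sign. With the block 1 rose and 5 fell of the MHC class II genes, 3 and 11 of the cDC2 markers, 3 and 6 of glycolysis, 0 and 1 of B cell, 1 and 3 of T cell, 2 and 1 of NK cell, 1 and 4 of macrophage and 4 and 2 of monocyte genes. By fry 9 lists passed.

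In WT cDC2, 426 genes rose and 705 fell on activation, and with the replicate number as a block 1222 and 2569. Centring each array on its median gave 632 and 272, quantile normalization again 462 and 466, and a log2 difference of at least 1 as well 233 and 145. Without WT resting replicates 1 and 2 and WT activated replicates 1 and 2 they were 94 and 56, 318 and 232, 173 and 140, and 47 and 16. The direction of the majority thus depended on the scaling, the size of change and each array. Of the 20 genes of largest change, 11 passed whichever of these arrays was left out (Cxcl9, Iigp1, Hamp, Irf8, Calhm6, Tbx21, Il6, Tnfsf15, Upp1, Slc43a2 and Chst2), and without WT activated replicate 2 the other 9 were lost.

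Activation of DKO cDC2 (2 arrays against 2) gave the response in cells without BATF and BATF3. Cxcl9 rose by 5.50 ± 0.32, Iigp1 by 5.43 ± 0.35, Cxcl10 by 5.18 ± 0.60, Tnfsf15 by 4.54 ± 0.19 and Calhm6 by 4.47 ± 0.31. Further increases were those of Gbp7 at 4.44 ± 0.58, Cxcl11 at 4.35 ± 0.19, Il6 at 4.33 ± 0.16, Trim30d at 4.17 ± 0.69 and Phxr4 at 4.16 ± 0.48 (adjusted p from 2.4e-04 to 0.0151). The largest decreases were those of Dcstamp at -3.30 ± 0.67, Ceacam1 at -3.16 ± 0.49, Scd2 at -2.74 ± 0.46, Lipa at -2.70 ± 0.37 and Acss2 at -2.58 ± 0.28. With them were Myo1f at -2.47 ± 0.28, Klrd1 at -2.43 ± 0.61, Foxred2 at -2.35 ± 0.18, Dpp7 at -2.27 ± 0.17 and Car2, also on the erythroid list, at -2.25 ± 0.35 (adjusted p from 0.00222 to 0.0486). Irf8 rose by 3.92 ± 0.33 (adjusted p = 0.00314), Batf2 by 1.56 ± 0.16 (adjusted p = 0.00458) and Irf4 by 1.19 ± 0.23 (adjusted p = 0.0227), while the deleted genes stood at -0.04 ± 0.54 (Batf) and -0.03 ± 0.45 (Batf3).

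Interferon-stimulated genes rose in 15 of 30 members in DKO (24 adjusted over the list alone, 30 with the block), with a median of 1.67 (adjusted p = 9.4e-17; estimated 0.232). Among them were Cmpk2 at 3.75 ± 0.57, Ifit2 at 3.18 ± 0.36 and Mx2 at 2.86 ± 0.36. IFN-gamma-responsive genes rose in 15 of 18 (17 adjusted over the list alone), with a median of 1.98 (adjusted p = 2.1e-16; estimated 0.175) and Gbp4 at 3.92 ± 0.54. Cytokines rose in 12 of 29 (16 adjusted over the list alone, 20 with the block), with a median of 1.18 (adjusted p = 2.2e-12; estimated 0.175). NF-kappaB genes rose in 7 of 24 (11 adjusted over the list alone; 14, and 1 lower, with the block), with a median of 0.51 (adjusted p = 6.3e-08; estimated 0.175), with Nfkbiz at 2.57 ± 0.17 and Tnfaip2 at 2.42 ± 0.32. Maturation genes had a median of 0.28 (adjusted p = 0.00129; estimated 0.441). Of 25 members 6 rose and 1 fell (7 and 4 adjusted over the list alone; 13 and 4 with the block), among them Il15ra at 2.68 ± 0.38, Cd70 at 2.0 ± 0.33, Cd40 at 1.54 ± 0.37 and Cd80 at 1.18 ± 0.12. MHC class I genes had a median of 0.39 (adjusted p = 0.00152; estimated 0.37). Of 17 members 2 rose (5 adjusted over the list alone; 9, and 1 lower, with the block), Nlrc5 at 1.33 ± 0.31 and Erap1 at 0.79 ± 0.19. Leaving out DKO resting replicate 1, the maturation median was 0.14, and without DKO activated replicate 2 the maturation and MHC class I medians were 0.17 and 0.25.

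Cholesterol synthesis genes fell in 8 of 20 members (12 adjusted over the list alone, 13 with the block), with a median of -0.50 (adjusted p = 4.3e-04; estimated 0.347), with Dhcr7 at -1.61 ± 0.20 and Mvd at -1.54 ± 0.20. Cell cycle genes fell in 6 of 28 (8 adjusted over the list alone; 18, and 1 higher, with the block), with a median of -0.48 (adjusted p = 0.0026; estimated 0.583). Among them were Ccna2 at -1.23 ± 0.17 and Plk1 at -1.12. The AP-1 and BATF list had a median of 0.22 (adjusted p = 4.9e-04; estimated 0.195). Of 22 members 5 rose and 1 fell, as many adjusted over the list alone and 9 and 3 with the block, with Mafk at 1.5 ± 0.17. Immediate early genes had a median of 0.38 (adjusted p = 4.9e-04; estimated 0.232). Of 27 members 4 rose, as many adjusted over the list alone and 13, with 2 lower, with the block, among them Dusp2 at 1.34 ± 0.17. Dendritic cell transcription factors had a median of 0.13 (adjusted p = 0.0143; estimated 0.232). Of 24 members 4 rose and 1 fell (6 and 2 adjusted over the list alone; 8 and 3 with the block), among them Tcf4 at 2.20 ± 0.16 and Mycl at 1.80 ± 0.16. The cDC1 marker list had a median of 0.03 (adjusted p = 0.00657; estimated 0.175). Of 29 members 4 rose, as many adjusted over the list alone and 7, with 2 lower, with the block. The 4 were Irf8, Gpr33 at 3.36 ± 0.35, Ifi205 at 2.37 ± 0.33 and Apol7c at 2.02 ± 0.48. With DKO resting replicate 1 left out, the medians were 0.40 for the AP-1 list, 0.21 for the transcription factors and just below 0 for cDC1 markers (adjusted p = 0.0183). With DKO resting replicate 2 left out, they were 0.10 for immediate early and -0.25 for cell cycle genes. They were -0.30 for cell cycle genes without DKO activated replicate 1, and without DKO activated replicate 2 0.34 for the AP-1 list and 0.19 for immediate early genes.

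The other 10 lists did not pass in DKO activation. MHC class II genes had a median of -0.15, with 3 that fell, led by Ctsd at -1.33 ± 0.18, and H2-DMa, at 0.42 ± 0.10, that rose. Of the cDC2 markers (median -0.34) 7 fell and 2 rose, among them Tbx21 at 3.68 ± 0.35 and Ltb at -1.49 ± 0.30. Glycolysis genes stood at -0.23 against a mean of 0.04, with 2 that rose, Hk2 at 2.29 ± 0.22 and Hk3, and 2 that fell. Plasmacytoid genes stood at -0.03 (2 rose, 2 fell), with Lag3 at 2.41 ± 0.30 and Spib at -1.33 ± 0.16, a test that pointed up and a median that changed sign with another scaling. B cell genes stood at 0.10, with Cd37 at -0.50 ± 0.12 and a mean just below 0, and T cell genes at -0.19 (1 rose, 2 fell), with Il7r at -1.01 ± 0.23. NK cell genes had a median of 0.02 against a mean of -0.06, with Klrd1 lower, and macrophage genes one of 0.11 against a mean of -0.25, with Spic at -1.21 and Treml4 at -1.01. Monocyte genes stood at 0.33, with Itga4 at 0.77 ± 0.16, Spn at -0.69 ± 0.11 and Treml4. Neutrophil genes stood at 0.13 and passed without DKO activated replicate 1 (0.39, adjusted p = 0.013). With the block 2 rose and 5 fell of the MHC class II genes, 4 and 11 of the cDC2 markers, 3 and 7 of glycolysis, 3 and 4 of plasmacytoid, 1 and 2 of B cell, 2 and 1 of NK cell, 0 and 4 of macrophage, 5 and 2 of monocyte and 0 and 1 of neutrophil genes. By fry 12 lists passed. In all, 624 genes rose and 848 fell, and 1393 and 2687 with the replicate number as a block. Centring each array on its median gave 806 and 480 and a log2 difference of at least 1 as well 367 and 194. Without DKO resting replicates 1 and 2 and DKO activated replicates 1 and 2 they were 271 and 265, 132 and 85, 160 and 115, and 289 and 328. Of the 20 genes of largest change 9 passed whichever of these arrays was left out (Cxcl9, Iigp1, Tnfsf15, Calhm6, Cxcl11, Il6, Acss2, Foxred2 and Dpp7).

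Whether the response to activation differs by genotype was tested as the interaction (DKO response minus WT response). No gene passed: 0 by limma without the block and 0 with the replicate block, with 121 and 368 genes at an unadjusted p under 0.05. Those of smallest p with a larger response in DKO were Gprc5c at 1.09 ± 0.19, Plpp2 at 0.74 ± 0.14, Cxcl11 at 1.34 ± 0.26, Cd36 at 0.61 ± 0.13 and Hacd2 at 0.58 ± 0.13. Those with a smaller one were Sucnr1 at -1.17 ± 0.20, Arc at -0.96 ± 0.17, Pdcd1lg2 at -0.91 ± 0.19, Macrod2 at -0.66 ± 0.16 and Rasal1 at -0.64 ± 0.15, all at adjusted p = 1.00. Batf stood at -1.15 ± 0.77, Batf3 at -1.63 ± 0.64, Batf2 at 0.28, Irf4 at 0.33 and Irf8 at -0.12. Across the 10728 genes the WT and DKO responses, which share no array, correlated at r = 0.941 (genes are not independent replicates), with a slope of 1.08 of the DKO on the WT response. In 378 genes both rose, against 24.8 for independent lists, and in 519 both fell, against 55.7. None was called in opposite directions, with or without the replicate block.

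**Figure D3:**
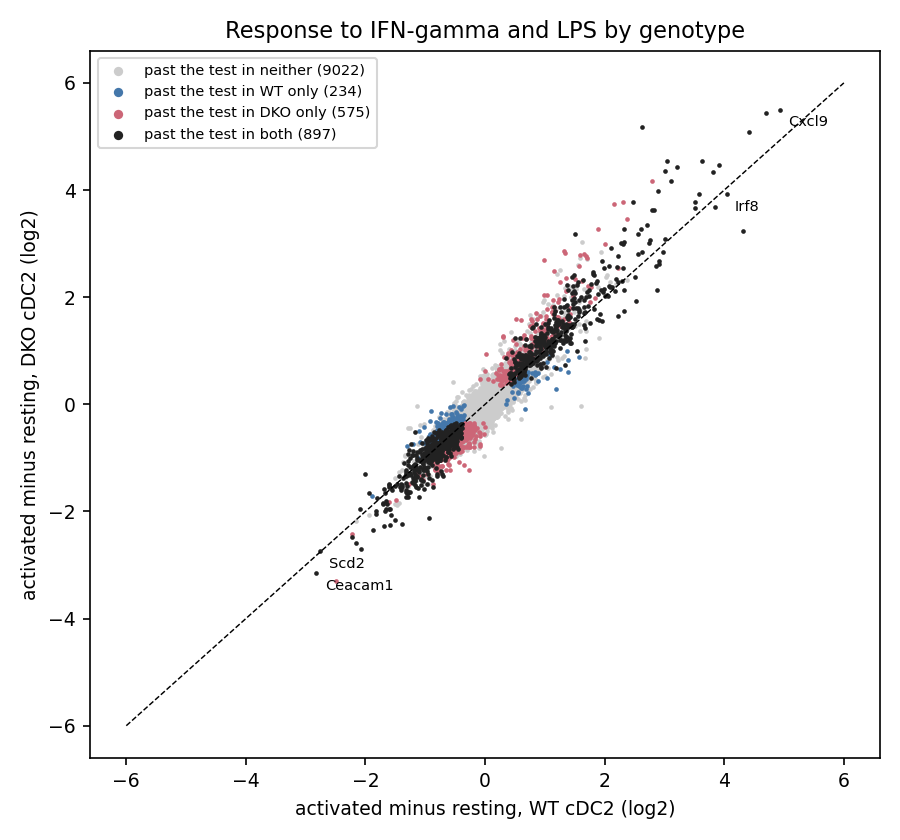
Log2 difference between activated and resting cDC2 for each of 10728 genes, in WT on the horizontal and DKO on the vertical axis, coloured by the genotypes in which a gene passed the test, with a dashed line of equality. The points lie along the line (r = 0.941 across genes), with Cxcl9 at 4.93 and 5.50 and Ceacam1 at -2.82 and -3.16.

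Of the lists, 4 passed in the interaction with the preset correlation, each at adjusted p = 0.877 with an estimated correlation. No member passed over all genes or adjusted over the list alone. Interferon-stimulated genes had a median of 0.72 (adjusted p = 2.8e-17), positive in all 30, with Rsad2 at 1.70 ± 0.49 and Ifit2 at 1.68 ± 0.51. IFN-gamma-responsive genes stood at 0.33 (adjusted p = 0.0334), cytokines at 0.30 (adjusted p = 4.4e-05) and cell cycle genes at -0.22 (adjusted p = 1.3e-06), with Ccna2 at -0.64 and Ccnb2 at -0.52. By fry 0 lists passed (adjusted p = 0.987). Without WT resting replicate 2 the medians were 0.14 for the interferon list (adjusted p = 0.0143), -0.05 for the IFN-gamma list (adjusted p = 0.874), 0.18 for cytokines and -0.39 for cell cycle genes. With WT resting replicate 1 left out they were 1.61, 0.68, 0.01 and -0.15, the last no longer past the threshold (adjusted p = 0.0983). MHC class I (0.39) and cholesterol synthesis genes (0.22) then passed. Without DKO resting replicate 1 the IFN-gamma call was lost (0.22, adjusted p = 0.184), the cell cycle median was -0.42 and B cell genes passed at 0.31. Without DKO resting replicate 2 the IFN-gamma (0.39), cytokine (0.09) and cell cycle (-0.07) calls were lost, each at adjusted p = 0.139. The cytokine call was also lost without DKO activated replicate 1 (0.21, adjusted p = 0.0846). The IFN-gamma call was lost without DKO activated replicate 2 (0.30, adjusted p = 0.49) and WT activated replicate 1 (0.11, adjusted p = 0.499). The other 18 lists did not pass (adjusted p from 0.103 to 0.96), with medians between -0.20 for NK cell genes and 0.16 for B cell genes. The medians, means and tests of the glycolysis, monocyte, neutrophil and immediate early lists did not share a sign, and another scaling turned those of NF-kappaB, cDC1 marker, transcription factor and monocyte genes.

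Resting cDC1 (1 array) were compared with resting WT cDC2 (2 arrays) as a reference for genes of either subset. In cDC1, P3h2 was higher by 6.54 ± 0.17, Clec9a, the receptor for exposed actin of dead cells, by 4.89 ± 0.19, Cd36 by 4.72 ± 0.12, the chemokine receptor gene Xcr1 by 4.70 ± 0.12 and Clec12a by 4.40 ± 0.29. Gpr141b was higher by 4.21 ± 0.17, Snx22 by 4.21 ± 0.11, P2ry14 by 3.99 ± 0.31, Aif1 by 3.88 ± 0.23 and Naaa by 3.87 ± 0.16 (adjusted p from 2.6e-05 to 0.00142). On the lower side were Mmp12 at -4.77 ± 1.05, Tlr7 at -4.67 ± 0.40, Irf4 at -4.53 ± 0.28, Clec4e at -4.45 ± 0.35 and Cybb at -4.33 ± 0.30. They were followed by Dscam at -4.23 ± 0.37, Ddx60 at -4.18 ± 0.58, Tm4sf19 at -4.09 ± 0.84, Rasgrp1 at -4.06 ± 0.34 and Siglecg at -3.80 ± 0.20 (adjusted p from 4.5e-04 to 0.0331). Irf8 was higher by 2.09 ± 0.41 (adjusted p = 0.0229), while Batf3 at 0.95 ± 0.55 (adjusted p = 0.311), Batf at 0.12 ± 0.67 and Batf2 at 0.08 did not pass.

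Of the cDC1 markers, 18 of 29 were higher and 0 lower in cDC1 (21 higher adjusted over the list alone), with a median of 2.09 (adjusted p = 7.5e-18; estimated 0.0117). Of the cDC2 markers, 13 of 25 were lower and 1, Clec12a, higher (15 and 1 adjusted over the list alone), with a median of -1.30 (adjusted p = 5.9e-08; estimated 0.0789). Among them was Sirpa at -3.04 ± 0.28. Cell cycle genes were higher in 14 of 28 (19 adjusted over the list alone), with a median of 0.93 (adjusted p = 2.1e-09; estimated 0.508). Among them were Cdk1 at 2.28 ± 0.31 and Ccnb2 at 2.02 ± 0.19. Interferon-stimulated genes were lower in 8 of 30, as many adjusted over the list alone, with a median of -1.55 (adjusted p = 5.9e-08; estimated 0.508). Among them were Rtp4 at -3.44 ± 0.36 and Ifih1 at -1.96, and the list median was -0.77 without WT resting replicate 2. NF-kappaB genes were lower in 5 of 24, as many adjusted over the list alone (median -0.46, adjusted p = 0.0018; estimated 0.508), with Nfkbiz at -1.22. Cholesterol synthesis genes were lower in 3 of 20 and in 9 adjusted over the list alone (median -0.44, adjusted p = 0.00877; estimated 0.508), with Idi1 at -1.21. Plasmacytoid genes were lower in 5 of 10 and higher in 1, as many adjusted over the list alone (median -0.88, adjusted p = 0.0198; estimated 0.387), with Ccr9 at -3.28 and Lag3 at -1.71. Without WT resting replicate 2 the cholesterol (-0.34, adjusted p = 0.134) and plasmacytoid (-0.64, adjusted p = 0.0611) calls were lost. By fry 5 lists passed, those of cDC1 markers, cDC2 markers, cell cycle, plasmacytoid and dendritic cell transcription factor genes.

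The other 15 lists did not pass between cDC1 and cDC2. Dendritic cell transcription factors (median -0.24) held Zeb2 at -2.26 ± 0.15 and Mycl at 1.28. The AP-1 and BATF list (0.10 against a mean of -0.29 and a test that pointed down) held Jun at -2.27 ± 0.15 and Fosl2 at -1.38, with 3 lower and 1 higher. Cytokines (-0.08) held Il12b at 3.09 ± 0.35 and Il1rn at -3.24 ± 0.32. IFN-gamma-responsive genes stood at -0.29, with 2 lower and Cxcl9 at 2.20 ± 0.40, and maturation genes at -0.19, with 5 lower and Pdcd1lg2 at 1.63. Both lists passed without WT resting replicate 1 (-0.36 and -0.40). Immediate early genes stood at -0.28 (adjusted p = 0.0573), MHC class I genes at 0.22, MHC class II genes at -0.05, with H2-DMa at 1.51 and 1 lower, and glycolysis genes at 0.24. Further medians were those of B cell genes at -0.08, with Blk at -2.83, T cell genes at -0.03, with Il7r at -3.12, and NK cell genes at 0.00, which took either sign with another scaling. Macrophage genes stood at -0.11, with Treml4 at 2.09 and Adgre1 at -1.79, monocyte genes at -0.28, with Ms4a4c at -3.26, and neutrophil genes at 0.16. In all 760 genes were higher and 704 lower in cDC1, and these 1464 calls became 798 without WT resting replicate 1 and 828 without WT resting replicate 2. Of the 20 genes named, 18 passed without either array, and Tm4sf19 was lost without each and Mmp12 without replicate 1. The cDC1 array itself has no replicate check.

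**Figure D4:**
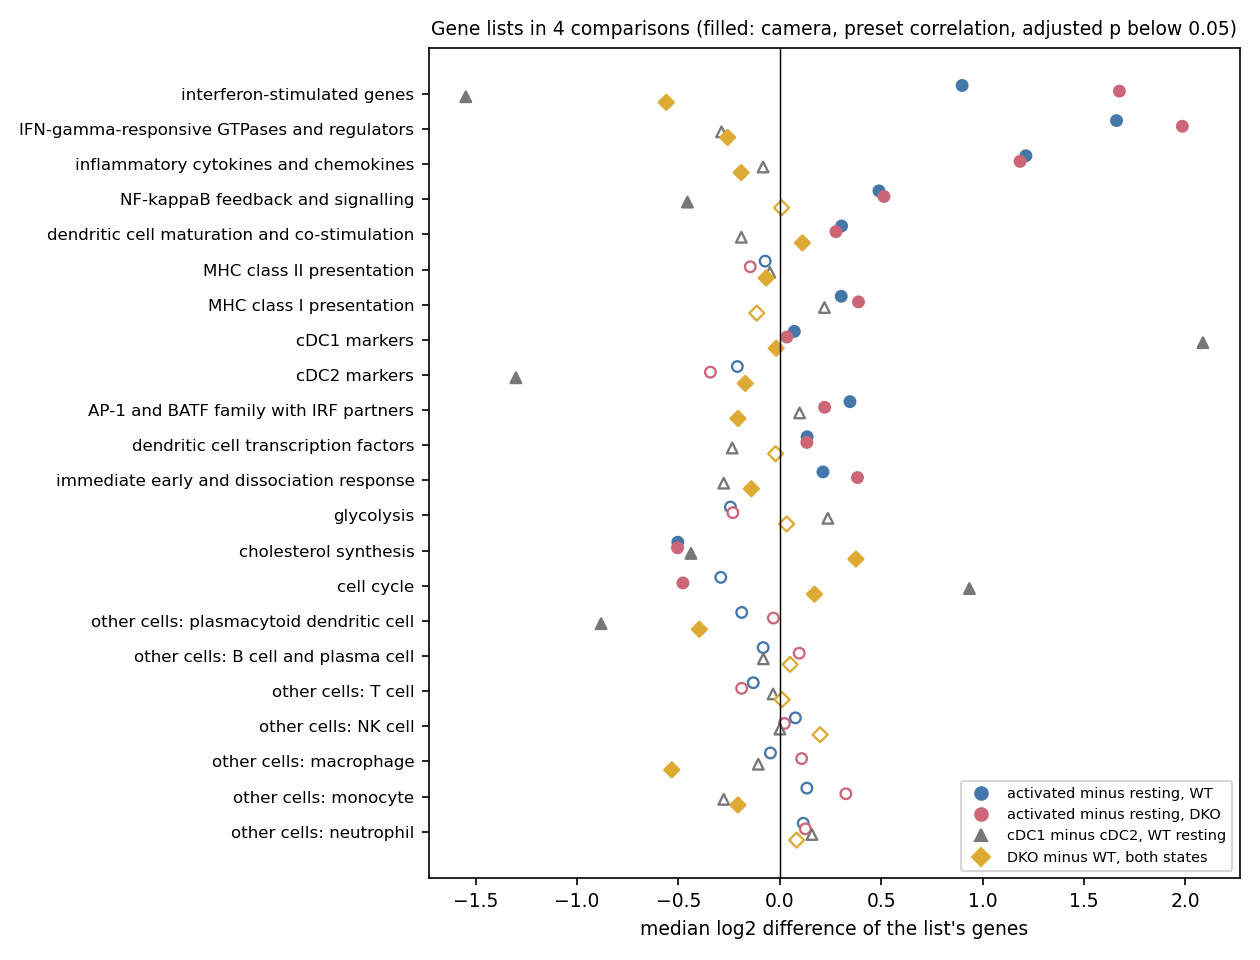
Median log2 difference of each gene list in 4 comparisons (WT activation, DKO activation, cDC1 against cDC2, and DKO against WT over both states), with filled symbols where camera's adjusted p with the preset correlation is below 0.05. The cDC1 marker list reaches 2.09 in cDC1, and cholesterol synthesis lies at -0.50 in both activations and at 0.37 in DKO against WT.

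The 100 genes highest in cDC1 and the 100 lowest, by log2 difference from cDC2, were then followed in the genotype comparison of activated cDC2, which shares no array with them. The question was whether the genes of either subset move in cDC2 without BATF and BATF3. The cDC2-high genes had a median of -0.15 in DKO against WT (33 higher, 67 lower; adjusted p = 7.6e-04) and the cDC1-high genes one of -0.06 (40 higher, 60 lower; adjusted p = 0.0434). Both were lost with an estimated correlation (adjusted p = 0.0987 for both) and with fry (adjusted p = 0.225 for both). With the replicate number as a block, fry passed for the cDC1-high genes (adjusted p = 0.0498). The cDC1-high call was lost without DKO activated replicates 1 and 2 (-0.0110 and -0.0773) and WT activated replicates 1 and 2 (-0.0407 and -0.0521). With the sets chosen again, it was also lost without WT resting replicate 2 (-0.0317). The cDC2-high call was lost without DKO activated replicate 2 (-0.13, adjusted p = 0.277). In resting cDC2, which share the 2 WT arrays with the choice of the genes, the medians were -0.21 for the cDC2-high genes (adjusted p = 9.9e-06; estimated 0.102) and -0.02 for the cDC1-high genes (adjusted p = 0.298, and by fry with the block 0.0474). They were -0.07 (from -0.17 to 0.03) and 0.03 (from -0.01 to 0.09) in 100 simulations of unchanged groups. Without DKO resting replicates 1 and 2 and WT resting replicates 1 and 2, the cDC2-high median at rest was -0.35, -0.12, -0.60 and -0.39 and the cDC1-high median 0.00, -0.06, -0.02 and 0.11, the latter never past the threshold. Across genes, which are not independent replicates, the cDC1 against cDC2 difference correlated with the resting genotype difference at r = 0.237, against 0.146 simulated, with a covariance of 0.0379 against 0.0203. With the activated genotype difference r was 0.104 and the covariance 0.0150. Split, the 2 shared arrays would leave 1 for each use, so they were not split, and part of the excess in resting cells may come from the shared controls.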

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

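The tests of a single array, of a shift shared by same-numbered arrays, of the genes that neighbour Batf and Batf3 and of DNA segments were chosen only after the result was seen. The tests of partial activation, normalization, dim probes and other splits were fixed before it.

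In 4 gene lists, the response to activation differed between DKO and WT cDC2 by the test of the difference itself with the preset correlation. The median difference of the responses was 0.72 for interferon-stimulated genes (adjusted p = 2.8e-17), 0.33 for IFN-gamma-responsive genes (adjusted p = 0.0334), 0.30 for inflammatory cytokines and chemokines (adjusted p = 4.4e-05) and -0.22 for cell cycle genes (adjusted p = 1.3e-06). None passed with an estimated correlation (adjusted p = 0.877 for each) or with fry.

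The first pattern is the interferon-stimulated list, lower in DKO than WT at rest (-0.98) and so with a larger DKO response. WT resting replicate 2 lay 1.38 above replicate 1 on this list, against 0.28 between the resting DKO arrays. Without that array the median was -0.20, with 21 of 30 genes lower, and passed with the preset correlation but not with an estimated one or with fry. That array as the whole source therefore cannot be told apart from a smaller difference without it. Partial activation of that array by IFN-gamma and LPS together is argued against by the 18 cytokine and NF-kappaB genes called up in DKO. They reached -1.94% of their DKO response in WT replicate 2 minus replicate 1 (quartiles -18.2% and 14.7%), against 33.5% for the 15 interferon genes. Less the same difference between the resting DKO arrays, which carries the shift shared by the numbers, they reached 13.7% (upper quartile 25.4%), against 51.5%. The 609 other genes called up in DKO reached 14.3% (quartiles -4.49% and 35.1%), or 21.9% less the DKO difference, so a response to interferon alone is not excluded. On that array plasmacytoid and NK cell genes lay 0.41 and 0.31 above replicate 1 (0.11 and -0.03 in DKO) and B and T cell genes at -0.20 and -0.14. NK cell genes averaged 7.54 on it but 7.84 and 7.81 in resting DKO, unlike the interferon list. A lower interferon tone without BATF and BATF3, interferon exposure of 1 sample and plasmacytoid or NK cells left in it by the sort stay open and untested.

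The second pattern is that arrays with the same replicate number deviate together. The lowest of the 6 correlations across genes was 0.454, as a shift shared by arrays of the same number would give, for example from a shared day or sort, which the labels do not name. Noise of dim probes is argued against as the source, since over the brightest genes alone it was 0.505. The normalization used by the authors cannot be told apart from other sources: the arrays already shared a distribution, so quantile normalization again (lowest correlation 0.455) could not undo it. No biological explanation was tested.

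The third pattern is that some genes differ by genotype in both states. Of the 10 tested genes on each side of Batf and Batf3, 4 of 40 were called with the replicate number as a block (Jdp2 at -0.53, Erg28 at 0.54, Fam71a at -0.40 and Atf3 at -0.71), against a mean of 2.21 and a 95th percentile of 5 in 10000 random pairs of windows. DNA of the flanks that came with the deleted genes therefore cannot be told apart from none by these counts. DNA segments that differ between the mouse lines also cannot be told apart from none: 11 pairs of the 100 genes of smallest p lay within 5 genes of each other, as did 11 for activation, and 4.61 in random lists. Loss of BATF and BATF3 themselves stays open for all of these genes.

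The 35 splits of the 8 cDC2 arrays into 4 and 4 had their own fit. Genotype gave 29 calls in it, against 2 above (791 against 599 with the block). As many or more came from 3 splits: genotype, state (3760) and replicate number (1505). All others gave 0 by limma. Since state follows the activation, the 35 are too few for a share under 0.05. The count for replicate numbers points to a structure of the samples. With the block, the highest other gave 5068. Of the 8 splits that part all 4 same-numbered pairs, also too few for a share under 0.05, the highest other gave 0.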

How the results depend on the processing

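All alternatives here were chosen before the result was seen, except the list without Batf and Batf3, one of the tests chosen after it.

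With the replicate number as a block, the counts of genes past the threshold were 79 for genotype at rest (against 2), 61 in activated cells (against 2), 599 over both states (against 2), 3791 for activation in WT (against 1131) and 4080 in DKO (against 1472). The block ended 2 list calls and added 4, all named beside the results. With only the arrays of the groups compared, the counts were 0 by limma at rest (630 genes at an unadjusted p under 0.05), 0 in activated cells (508 genes), 5 for WT activation and 757 for DKO activation, where fewer arrays estimate the spread. With a log2 difference of at least 1 as well, 378 genes were called for WT activation, 561 for DKO activation and 645 between cDC1 and cDC2. No other alternative with all arrays moved the total of a comparison by over 1.5 times. By direction, centring each array moved the genes that fell on activation from 705 to 272 in WT and from 848 to 480 in DKO, and quantile normalization again those in WT to 466.

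Leaving out 1 array at a time, the counts ran from 0 to 6 for genotype at rest, were 0 each time in activated cells, and ran from 2 to 4 over both states, from 63 to 550 for WT activation, from 217 to 617 for DKO activation and from 798 to 828 between cDC1 and cDC2. A group left with 1 array was assumed to vary as the others do. In the interaction 0 genes passed by limma under every alternative, with 86 to 403 at an unadjusted p under 0.05. Over all alternatives together, the values of named genes past the threshold kept their side of it and their direction 1945 times, fell short of it 427 times and never reversed.

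With an estimated correlation, 0 lists passed in each genotype comparison, in each activation and in the interaction, and 1 between cDC1 and cDC2. By fry, 0 passed for genotype at rest, 0 in activated cells, 4 over both states and 0 in the interaction. Without the brightness filter, 12 lists passed between cDC1 and cDC2, against 7. Without 1 array, the number of lists ran from 4 to 8 for genotype in activated cells and from 1 to 5 in the interaction. The MHC class I list at rest ran from -0.43 to 0.16 and turned without WT resting replicate 2, as did the IFN-gamma list in the interaction, which ran from -0.0502 to 0.68. The cDC1-high set in activated cells, at -0.0619, and the cDC2-high set, at -0.15, no longer passed with an estimated correlation or with fry, and without 1 array they ran from -0.0773 to -0.0110 and from -0.21 to -0.11. For these lists and sets the cause was not tested. The AP-1 and BATF list without Batf and Batf3 had medians of -0.21 at rest (adjusted p = 0.00202, estimated 0.225) and -0.16 in activated cells (adjusted p = 0.00666, estimated 0.287). Over both states it stood at -0.18 (adjusted p = 0.00123, estimated 0.22). It held Jdp2 and Atf3, neighbours of the deleted genes, so flanking DNA stays open.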

Other observations

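The gene groups and tests in this part were chosen only after the result was seen, the groups from among the genes that differ, so that their counts describe these genes and test nothing.

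Between arrays of replicate numbers 1 and 2, across all 4 cDC2 groups, 1033 genes were higher in number 1 and 1355 in number 2. Genes of the response to amino acid shortage, most of which make or import amino acids or charge tRNAs, were higher in number 1 in 17 of 18 members, with a median of -0.78 (number 2 minus number 1). Among them were Asns at -1.47 ± 0.08, Slc7a5 at -1.58 ± 0.07 and Shmt2 at -1.64 ± 0.09. The exception was Wars, which IFN-gamma also induces, at 0.45 ± 0.10. Heat shock genes, which code for chaperones, were higher in number 2 in 12 of 12 members, with a median of 0.69, Hsph1 at 1.83 ± 0.12 and Hspa1a at 1.32 ± 0.07. Of the 22 lists, 8 passed between the numbers with the preset correlation (adjusted p from 0.00395 to 0.0337) and none with an estimated one (lowest adjusted p = 0.573). Interferon, IFN-gamma, maturation, MHC class I and cell cycle genes were higher in number 2, and cytokine, AP-1 and B cell genes in number 1.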
